A study of Homo sapiens with 2 samples.

How the data were processed

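The series holds 2 arrays of biotin-labelled complementary RNA from PC-3 cells. For 1 array the cells had a control shRNA vector, and for the other a vector against SHISA2. Groups were taken from the sample titles. The titles carry the prefix si, which usually stands for small interfering RNA, while the design text uses the same names for transfected vectors that express shRNA, and the text here follows the design. Per the labels' protocols, total RNA was isolated with TRIzol, purified on columns, checked on a Bioanalyzer and labelled from 250 ng with the manufacturer's 3' in vitro transcription kit. How many cultures each RNA came from, how they were grown or when they were harvested is not given in the sources used here.

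The deposited values are probe-set intensities (signals) on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The version is not given in the sources used here. MAS5 compares perfect-match with mismatch probes, so signals near background are noisy and carry little information on the order of genes. In the deposited intensities the mean after trimming 2% of probe sets at each end was 500.1 in both arrays, as after scaling each array by 1 factor, and no further scaling was applied in the main setting. The median signal was 45.6 in the control and 50.3 in the knockdown array, and the 75th percentile 388.6 and 386.2. Signals above the floor made up 49.2% and 50.8% of probe sets. Over the 29305 measured probe sets the log2 signals of the 2 arrays had a Pearson correlation of 0.959 (across probe sets, which are not independent replicates), and the median log2 ratio was 0.02 with an SD of 0.37. Detection calls were not used here.

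Of the 54675 probe sets, 62 were controls and were kept out of the gene analysis. The annotation table used here lists 42898 probe sets. Of these 41097 have 1 gene symbol and 1801 have several, and 11777 probe sets of the array are not listed. Gene identifiers of 41043 probe sets matched the RefSeq gene table of assembly GRCh38.p14, which was used for names only, and no symbol changed. Probe sets with several genes or none name no gene, so some genes of the lists have no value. Of the 13522 unnamed probe sets 4798 were measured, 87 of them at least 2-fold higher and 19 at least 2-fold lower in the knockdown array. With the floor raised to 387.3, 1479 unnamed ones were measured, of which 1 was at least 2-fold higher and 0 were lower. Genome positions are not given because no build is named for the files.

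Signals under the floor, the median of all non-control signals of both arrays (47.9), were raised to it. A probe set counted as measured if its higher signal was above the floor. A gene was represented by its measured probe set with the highest mean log2 signal, and its value is the log2 ratio of knockdown over control. Where 1 of the 2 signals was at the floor the ratio is a bound and is written as at least. Of the 12931 measured genes, 6428 had several measured probe sets and 6503 had 1. The 2-fold threshold is a size, not a test. With 1 array per group no residual degrees of freedom exist, and no p-value was computed. The technical spread is the SD of the difference between the log2 ratios of the 2 brightest measured probe sets of a gene, divided by the square root of 2. It leaves out variation between cultures, extractions and arrays.

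Gene lists (33 lists, 647 different genes, 19 of them in more than 1 list) were fixed before the data were examined, for the Shisa and Wnt families, signalling, cell cycle, stress, metabolism, adhesion and other cell types. The median log2 ratio of each list with at least 5 measured genes was given its percentile among 10000 random lists of the same size, drawn with replacement from the same 10 bins of mean log2 signal. Outside the range means under the 2.5th or over the 97.5th percentile. Genes are named by a rule fixed at the same time: SHISA2 and every measured Shisa and Wnt ligand gene, up to 12 genes per direction with several measured probe sets that are all at least 2-fold apart in 1 direction, ranked by mean log2 ratio, 4 genes per direction read by exactly 1 measured probe set that is not of the _x_at or _s_at kind, and up to 4 members of each list with the largest ratios in size. Genes named outside this rule are marked in the text as named after their values were seen. Probe sets of the _x_at and _s_at kinds can share probes with other transcripts.

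Alternatives fixed in advance were median centring, quantile normalization, removal of a loess trend of the ratio on signal (span 0.3), floors at the 25th percentile (11.3) and the 75th percentile (387.3), no floor with a pseudocount of 1, the mean over a gene's measured probe sets, leaving out _x_at and _s_at probe sets, thresholds of 1.5-fold and 3-fold, and random lists not matched on signal. Added after the data were seen were 5 further gene lists, each with and without the genes that prompted it. The procedure was run on a simulated pair of arrays for this comparison over 12743 genes. The simulated noise was independent between probe sets, larger for dim ones, and held no variation between cultures or extractions. Changes of 1.5 or 2.5 on the log2 scale, large against their noise, were given to 200 genes chosen among bright ones. All were called at 2-fold (100%, 50 genes for each size and direction), which checks the code but not dim genes. Of 12543 unchanged genes 51 were called, and 0 of the 7707 with a mean signal above the 75th percentile of simulated probe sets. These counts hold for the simulated noise and give no rate of false calls in the real arrays. Of 200 unchanged lists 9 fell outside the range (4.5%), and 20 of 20 shifted lists, drawn from bright genes, were found. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.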

Results

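Gene expression was measured on 2 oligonucleotide arrays, each hybridised with RNA from PC-3 cells. PC-3 is a human prostate cancer line that was established from a bone metastasis and grows without androgen. Cells for 1 array had received a control short hairpin RNA (shRNA) vector, and cells for the other a vector against SHISA2. The series describes SHISA2 as more highly expressed in prostate cancer of high grade. The comparison asks which transcripts differ when SHISA2 is knocked down. Each array held 54675 probe sets, and 12931 named genes had a signal above the floor of 47.9 in at least 1 array. There were no replicates, so no difference below was tested against variation between cultures, and the number of arrays limits the precision of every value. As a technical yardstick, the SD of the difference in log2 ratio between 2 probe sets of the same gene, divided by the square root of 2, was 0.286, and 0.155 with the floor raised to 387.3. All log2 ratios are knockdown over control.

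SHISA2 was lower in the knockdown array. Its only probe set read 3536 in the control array and 1506 in the knockdown array, which is 42.6% of the control signal and 2.35-fold lower (log2 ratio -1.23). Shisa proteins are known to hold back the maturation of Frizzled and fibroblast growth factor receptors in the endoplasmic reticulum. Among the 7650 genes with both signals above 387.3, none had a lower ratio than SHISA2, and its ratio was 7.97 times 0.155 in size. Of the 401 genes with only the brighter signal above 387.3, 5 had a lower one: SPP1 (-1.69), TRIB2 (-1.57), SCEL (-1.57), HTRA1 (-1.41) and SLC14A1 (-1.26), of which all but SLC14A1 were named after their values were seen. With 1 probe set, the value could not be compared with a second one of the gene.

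Of the genes with both signals above 387.3, 5 were at least 2-fold higher and 4 at least 2-fold lower. Besides SHISA2, those on the lower side were ERMP1, an endoplasmic reticulum metallopeptidase, at 1900 against 4220 (log2 ratio -1.15), IGFBP4, a binding protein of insulin-like growth factors, at 519.7 against 1105 (-1.09), and NPNT, the matrix protein nephronectin, at 1087 against 2215 (-1.03). On the higher side stood IGFBP6, another binding protein of insulin-like growth factors, with a signal of 11925 in the knockdown array and 4848 in the control array (log2 ratio 1.30). AEN, a p53-induced nuclease, had a log2 ratio of 1.13, the interferon-induced chemokine CXCL11 1.07, CDKN2B, an inhibitor of G1 cyclin-dependent kinases, 1.01, and LCN2, the siderophore-binding protein lipocalin-2, 1.01. Both measured probe sets of ERMP1 were lower and both of CXCL11 higher. SHISA2, ERMP1 and AEN fell under the rule for named genes, and the other 6 were named after their values were seen.

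Over all measured genes, 119 were at least 2-fold higher and 73 at least 2-fold lower in the knockdown array. Among genes with several measured probe sets, 1 was at least 2-fold higher on all of them and 4 were at least 2-fold lower on all of them. The higher one was PDZK1IP1, a small membrane protein, with signals of 428.2 against 144.0 (log2 ratio 1.57, and 1.15 on its other probe set). SPARC, a secreted matrix protein, was lower at 56.8 against 293.1 (-2.37 and -1.52). The urea transporter SLC14A1 read 201.4 against 484.0 (-1.26 and -1.83), and TNFRSF11B, the decoy receptor osteoprotegerin, 92.6 against 204.9 (-1.15 and -1.27). ERMP1 was the fourth. Of genes read by 1 probe set, DHX58, an RNA helicase of the RIG-I family, was 4.01-fold higher (196.0 against 48.9, a control signal barely above the floor). ZNF865 was at least 3.88-fold, FLJ40288 at least 3.69-fold and the long noncoding RNA MIAT at least 3.44-fold higher, each with a control signal under the floor. PLEC, the cytoskeletal linker plectin, was at least 3.88-fold lower, with a knockdown signal under the floor. ADM2, a peptide hormone of the calcitonin family, had a log2 ratio of -1.88, the tubulin-associated TEDC2 -1.73 and ZSWIM9 -1.67, with knockdown signals of 51.4, 57.4 and 66.4, near the floor.

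These counts rest mostly on dim genes. In 103 of the 119 higher and 60 of the 73 lower genes the brighter of the 2 signals was at most 387.3, in 11 and 9 only the brighter one was above it, and 51 and 23 of the higher and lower genes are lower bounds because 1 signal lay under the floor. Raising the floor to 387.3 left 5 higher and 4 lower genes, and lowering it to 11.3 gave 1400 and 974. Of the calls, 62.0% were on the higher side as deposited, 58.3% after median centring (112 higher and 80 lower), 51.8% after quantile normalization (100 and 93) and 51.3% after a loess trend was removed (101 and 96). In 34 of the 48 such genes with several measured probe sets, every other probe set had the same sign (70.8%, Wilson 95% interval 56.8% to 81.8%). Without probe sets that can share probes between transcripts it was 18 of 31 (58.1%, 40.8% to 73.6%).

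**Figure D1:**
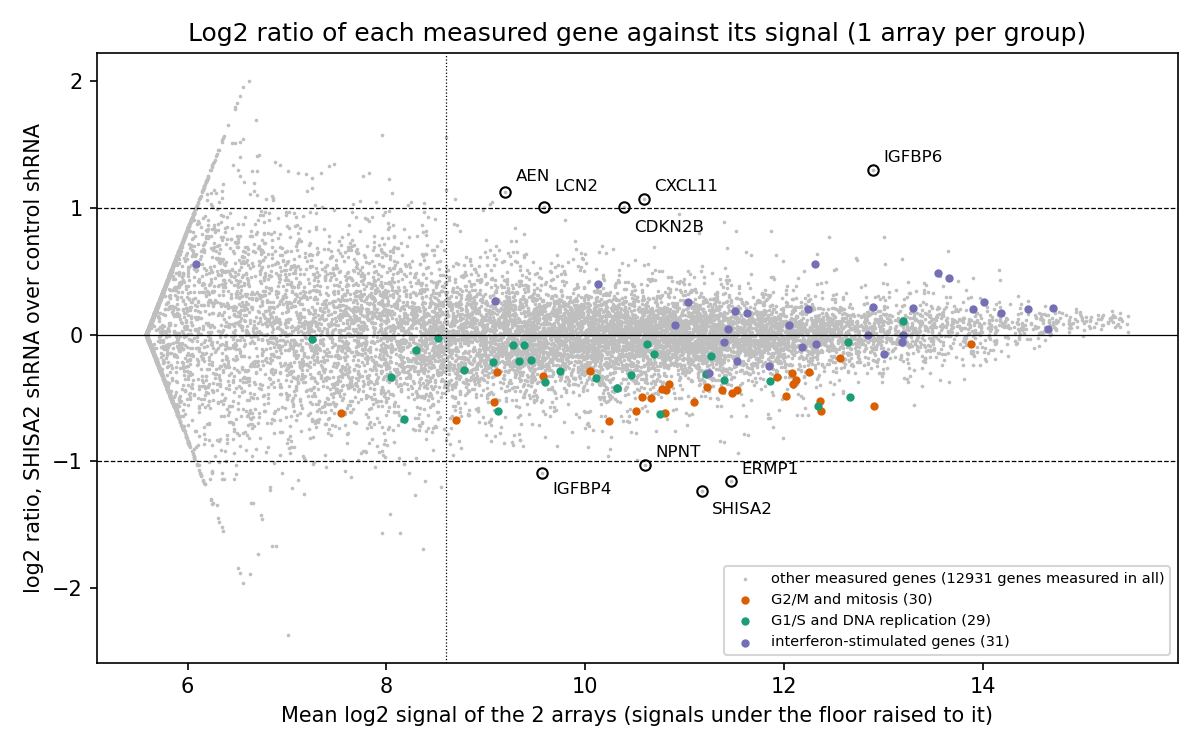
Log2 ratio of knockdown over control (vertical axis) against the mean log2 signal of the 2 arrays (horizontal axis) for the 12931 measured genes, 1 point per gene, with the cell cycle and interferon lists coloured. The dashed lines mark 2-fold, the dotted line marks a mean signal of 387.3, and circles mark the 9 genes at least 2-fold apart with both signals above 387.3, from SHISA2 at -1.23 to IGFBP6 at 1.30.

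Genes of the cell division cycle were lower together. All 30 measured members of the G2/M and mitosis list had log2 ratios below 0, with a median of -0.44. Among them were KIF23, a kinesin of cytokinesis (-0.68), the phosphatase CDC25C (-0.67, with 0.27 on its other probe set), cyclin A2, encoded by CCNA2 (-0.62), and the mitotic kinase PLK1 (-0.62). In the list of G1/S and DNA replication genes, 28 of 29 were below 0, with a median of -0.28. CDC45 (-0.67) and GINS1 (-0.63), parts of the replicative helicase, POLE2, a subunit of DNA polymerase epsilon (-0.60), and RRM2, a subunit of ribonucleotide reductase (-0.56), had the largest differences, and the histone mRNA binding protein SLBP was the exception at 0.11 and was named after its value was seen. None of the 59 genes reached 2-fold. Of all measured genes, 47.8% were below 0. Both medians lay below those of all 10000 random lists matched on signal, in the main setting and under the 3 other scalings.

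**Figure D2:**
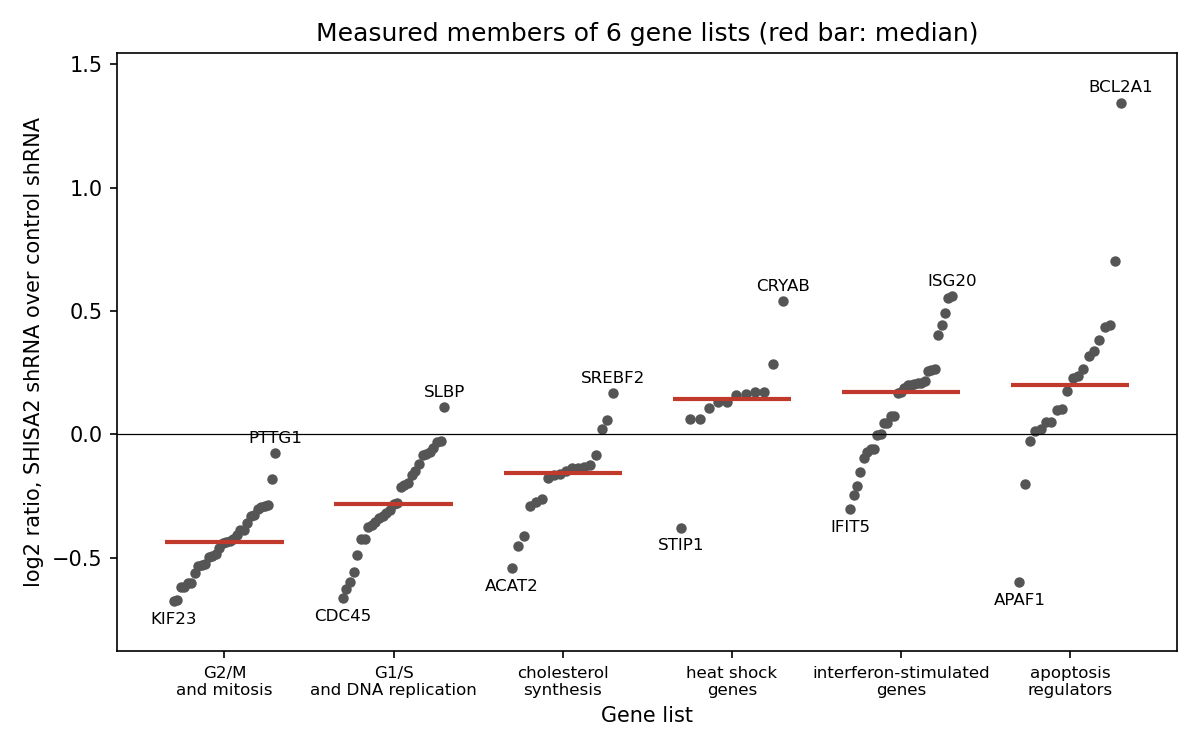
Log2 ratio of knockdown over control (vertical axis) of every measured member of 6 gene lists (horizontal axis), 1 point per gene in order of its ratio, with a red bar at the list median. The 30 G2/M genes all lie below 0 around a median of -0.44, and 22 of the 31 interferon-stimulated genes lie above 0 around a median of 0.17.

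Cholesterol synthesis genes were lower by a smaller amount, with 15 of 18 below 0 and a median of -0.15. ACAT2, which condenses acetyl-CoA (-0.54), DHCR7, the last reductase of the pathway (-0.45), the sterol dehydrogenase NSDHL (-0.41, and 0.06 on its other probe set) and squalene epoxidase, SQLE (-0.29), led the list. SREBF2, the transcription factor that drives these genes, was on the other side at 0.17 and was also named after its value was seen. The median fell at the 0.38th percentile of random lists. Fatty acid synthesis genes did not stand apart (6 of 12 below 0, median -0.03), although the desaturase SCD read -0.49 (probe sets from -0.73 to 0.68) and acetyl-CoA carboxylase, ACACA, 0.30.

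Genes that respond to interferon were slightly higher. The median over 31 interferon-stimulated genes was 0.17, with 22 above 0, and it lay above all 10000 random lists. ISG20, an antiviral exonuclease (0.56), IFIT2, an RNA-binding translation inhibitor (0.49), and OASL (0.44) were bright and higher, MX1 read 0.55 at signals of 82.1 against 55.9, and IFIT5 (-0.30) and OAS1 (-0.25) were lower. The last 2 were named after their values were seen. Among NF-kB cytokines and targets, 14 of 18 were above 0 with a median of 0.14 (99.0th percentile). NFKB2, a subunit of NF-kB itself (0.86, and 0.12 on its other probe set), interleukin-1 beta, IL1B (0.62, at signals of 83.4 against 54.2), the macrophage growth factor CSF1 (0.57) and interleukin-6, IL6 (0.54), had the largest ratios. The NF-kB list came within the random range in 4 of 9 alternatives, and the interferon list in none of them.

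Several stress and death lists were also above the random range. Of 20 apoptosis regulators 17 were above 0, with a median of 0.20. The higher members had opposite roles, with the survival protein BCL2A1 (1.34) next to the death-promoting HRK (0.70, and -0.08 on its other probe set) and PMAIP1 (0.45). The apoptosome scaffold APAF1 read -0.60, with probe sets from -0.60 to 0.29. Immediate early genes had a median of 0.17 with 14 of 16 above 0, among them FOSB (0.43), KLF4 (0.42) and JUNB (0.42), against -0.91 for KLF2. Heat shock genes had a median of 0.14 with 11 of 12 above 0, led by CRYAB (0.54) and the co-chaperone BAG3 (0.29), with STIP1 at -0.38 (0.13 on its other probe set). ATF4 and amino acid stress genes had a median of 0.10 with 14 of 19 above 0, including DDIT3 (0.34) and the serine pathway enzymes SHMT2 (0.29, with probe sets from -0.13 to 0.29) and PSPH (0.26), and NUPR1 at -1.04. The apoptosis, immediate early and heat shock lists came within the range without probe sets that can share probes. The apoptosis list also did so with the floor raised to 387.3, the ATF4 list when a gene's probe sets were averaged, and the ATF4 and heat shock lists against unmatched random lists.

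The p53 target genes had a median of -0.02, with AEN (1.13) at one end and TP53I3 (-0.47), the DNA repair protein DDB2 (-0.44) and SESN1 (-0.43) at the other. With the floor raised to 387.3, 13 members were measured and their median was 0.16, at the 99.4th percentile, but 7 were above 0 and 6 below. PC-3 cells are known to lack functional p53. Unfolded protein response chaperones had a median of -0.05, with the disulfide isomerase PDIA4 lowest at -0.35. That list was within the random range in the main setting and below it after quantile normalization and after the loess trend was removed.

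**Figure D3:**
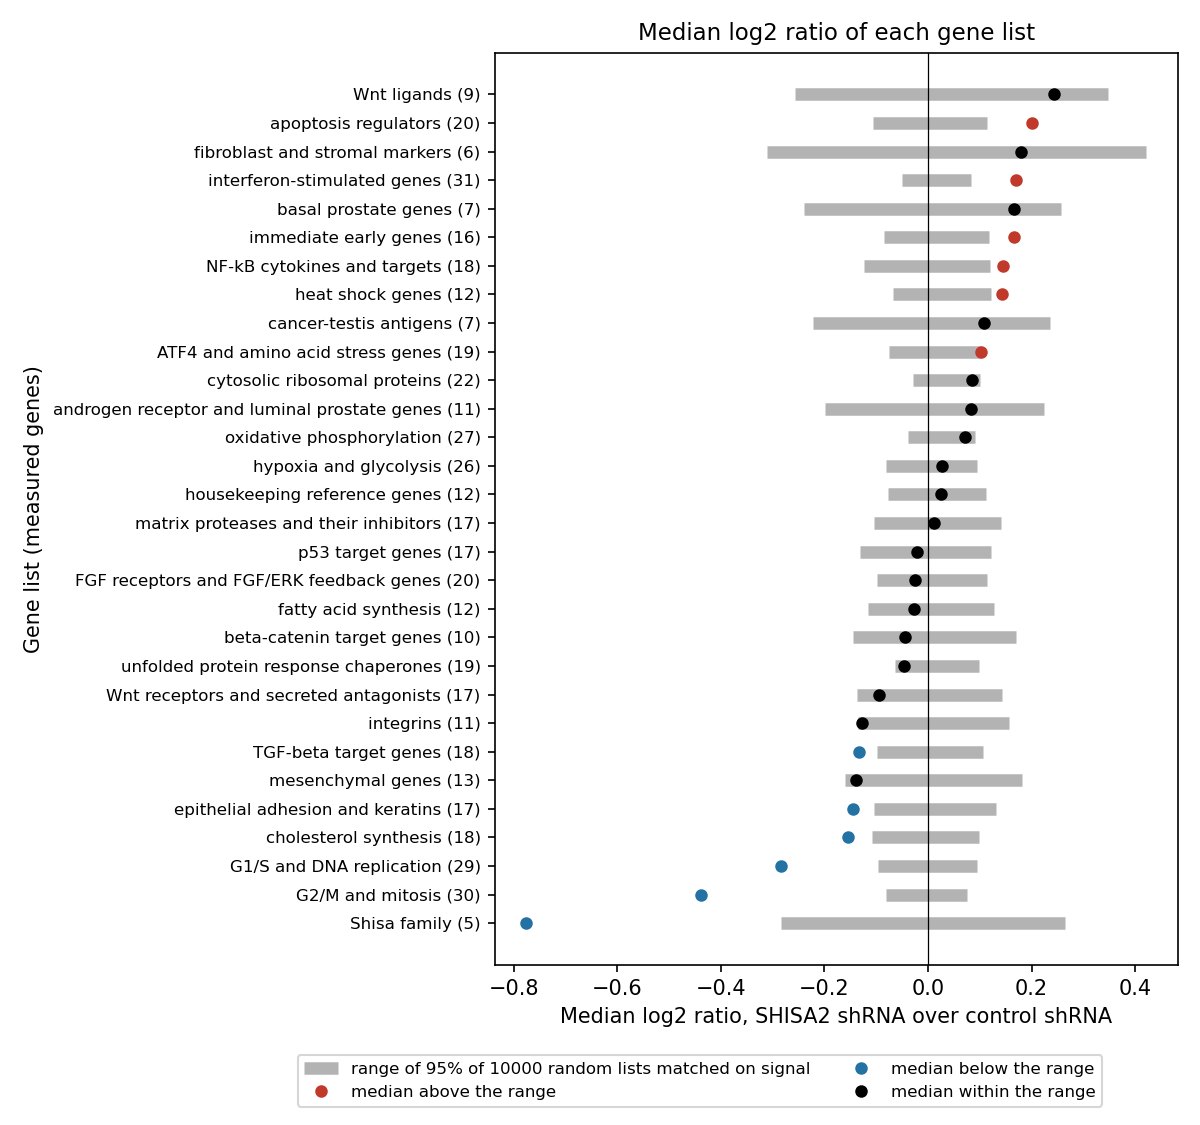
Median log2 ratio of knockdown over control (horizontal axis) of the 30 gene lists with at least 5 measured genes (vertical axis, number of measured genes in brackets), with grey bars for the range of 95% of 10000 random lists matched on signal. The G2/M list at -0.44 and the Shisa family at -0.78 lie farthest below their ranges, the latter including SHISA2 itself, and the apoptosis list at 0.20 has the highest median of those above.

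Within the Shisa family, 4 of 5 measured genes were below 0. SHISA3 read 1117 against 1914 (-0.78) on a probe set that can share probes with other transcripts, SHISA8 -0.82 at signals of 66.0 against 116.8, SHISA5 -0.02 and SHISA4 0.40. The list median of -0.78 includes the targeted gene. Without shared probe sets, and with the floor raised to 387.3, 3 members were measured, too few to rank the list.

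Wnt ligands, the secreted proteins that Frizzled receptors bind, had a median of 0.24, within the random range, with 6 of 9 above 0. WNT2B (0.87), WNT9A (0.84), WNT6 (0.56), WNT7B (0.24) and WNT7A (0.17) were all dim, with signals of at most 252.7, and WNT16 was at least 1.53-fold higher from under the floor. WNT10A and WNT10B were at least 1.21-fold and 1.09-fold lower. WNT5B, the brightest ligand, read 1382 against 1475 (-0.09). Its other measured probe set had a log2 ratio of 1.16, at 110.8 against 49.6, a control signal barely above the floor. WNT5A was not above the floor on either of its probe sets. Wnt receptors and secreted antagonists had a median of -0.09 with 12 of 17 below 0, including the receptors FZD10 (-0.83), ROR1 (-0.78) and FZD2 (-0.68, and 0.05 on its other probe set), and FZD4 at 0.65. Beta-catenin target genes had a median of -0.04. Their largest ratios were 0.28 for MYC, -0.28 for NOTUM, 0.25 for NKD2 and -0.19 for ZNRF3. None of these 3 lists left the random range in the main setting. Without probe sets that can share probes, the 5 measured ligands had a median of 0.56 (99.6th percentile) and the receptors and antagonists one of -0.18 (2.28th percentile), both outside their ranges. The ligand list was also above its range when probe sets were averaged (0.53), with the lower floor (0.52) and against unmatched random lists. The averaged median of 0.53 was the value of WNT5B itself, the mean of its bright and its near-floor probe set.

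FGF receptors and FGF/ERK feedback genes had 10 members above and 10 below 0, with a median of -0.02. SPRY1, an inhibitor of receptor tyrosine kinase signalling, read -1.15 (-0.07 on its other probe set), FGFR4 -0.93 (-0.03 on the other), the transcription factor ETV4 -0.85 and FGFR2 0.64 (0.01 on the other).

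TGF-beta target genes had a median of -0.13 (0.56th percentile, 11 of 18 below 0), with the collagen gene COL4A1 at -0.79 (-0.04 on its other probe set), the inhibitory SMAD6 at -0.71 and the transcription regulator ID2 at 0.69. Epithelial adhesion and keratin genes had a median of -0.14 (12 of 17 below 0), with CLDN3 at -0.51, DSC2 at -0.41 and KRT7 at 0.44, and the transcription factor OVOL1 at least 2.05-fold higher. The mesenchymal list had nearly the same median (-0.14, 11 of 13 below 0) but lay within its random range. It held SPARC, fibronectin, FN1 (-0.98, with probe sets from -1.28 to 0.18), S100A4 (0.65) and N-cadherin, CDH2 (-0.47). Integrins had a median of -0.13 at the 3.14th percentile (9 of 11 below 0), and ITGB3 was lower on all 6 of its measured probe sets (-1.45 to -0.16). ITGA3 read -0.44, ITGB5 -0.36 (probe sets from -0.85 to 0.12) and ITGAV -0.27. Matrix proteases and their inhibitors had a median of 0.01, with MMP7 at least 1.99-fold lower, TIMP2 at -0.58, MMP9 at 0.61 and TIMP3 at least 1.40-fold higher. The TGF-beta list came within the range with the floor raised to 387.3 and when probe sets were averaged, and the epithelial list without probe sets that can share probes. The integrin list lay below the range with the floor raised to 387.3 (1.10th percentile), without probe sets that can share probes, and after quantile normalization and loess.

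The hypoxia, oxidative phosphorylation, ribosomal protein and housekeeping lists stayed within their ranges in the main setting. Hypoxia and glycolysis genes had a median of 0.03, which was on the other side of 0 after quantile normalization and loess, with the glucose transporter SLC2A1 at 1.05, ENO2 at -0.51, ANGPTL4 at 0.47 (-0.28 on its other probe set) and ADM at 0.45. Oxidative phosphorylation genes had a median of 0.07 and single ratios from -0.13 (NDUFA9) to 0.25 (NDUFA1). Cytosolic ribosomal protein genes had a median of 0.09, with 22 of 22 above 0 as deposited, but 14 of 22 after loess and 11 of 22 after quantile normalization, where the median was below 0. Housekeeping reference genes had a median of 0.03, with 7 of 12 above 0 as deposited and 3 of 12 after quantile normalization or loess, and the largest single ratio was -0.36 for GUSB. The ratio of 3' to 5' signal was 5.0 in the control and 4.8 in the knockdown array for ACTB, and 1.55 and 1.36 for GAPDH. The 18 hybridisation controls had a median log2 ratio of 0.04 and the 24 poly-A controls one of 0.06. The 3 probe sets for 18S ribosomal RNA read -0.52 to -0.21. The bright control probe sets for the large-subunit ribosomal RNA went the other way, at 12710 against 8699.4 (0.55) and 5582 against 4810.6 (0.21). The dim probe set for that RNA, at 30 against 13.8, was under the floor in both arrays. The ribosomal RNA controls thus differed in direction.

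Few markers of other cell types were measured. Of the leukocyte markers 4 were measured, of the endothelial markers 3 and of the neuroendocrine genes 3, too few to rank. Among them CD79A read 0.59, the endothelial cadherin CDH5 0.75, the endothelial adhesion molecule ESAM -0.06 at signals of 500.9 against 522.6, and the secretogranin SCG2 was at least 2.26-fold lower from a signal of 108.2. Fibroblast and stromal markers had a median of 0.18 within a wide random range, with COL6A3 at -0.94, COL1A1 at 577.0 against 787.2 (-0.45, with probe sets from -0.45 to 0.92) and desmin, DES, at least 1.96-fold higher from under the floor. Luminal prostate genes had a median of 0.08, with FOXA1 at -0.42 and the kallikreins KLK4 at least 2.10-fold and KLK2 at least 1.49-fold higher. Basal prostate genes had a median of 0.17 (0.29 and above the random range without probe sets that can share probes) with 7 of 7 above 0. The bright ones were the laminin gene LAMB3 (2988 against 1713, 0.80), S100A2 (0.23) and DST (0.06). KRT5, KRT14 and TRIM29 had control signals under the floor. Being measured, they could only have ratios above 0, so their signs carry no information. DST, KRT5 and KRT14 were named after their values were seen. Cancer-testis antigens had a median of 0.11 with 7 of 7 above 0, led by MAGEA12 (0.46). Among them PAGE1 and MAGEC2, the latter named after its value was seen, had control signals under the floor. The signs of these genes were likewise fixed by the floor.

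Of the 30 lists with enough measured genes, 6 lay above and 6 below their random ranges. The Shisa family is among the latter, and its place is partly set by SHISA2 itself, without which 4 measured genes are too few to rank. Random lists hold genes that are not co-regulated, so a percentile describes these 2 arrays and is not a p-value.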

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

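The counts of 2-fold genes depended on the floor and the size threshold, by construction of these alternatives. The numbers of lists outside the range moved less, but which lists were outside changed. With the floor at the 25th percentile there were 1400 higher and 974 lower genes, the technical SD was 0.599 and the share of 2-fold genes with all probe sets in 1 direction was 46.5%. With no floor the values were 2149, 1706, 0.917 and 40.3%, and with the floor at the 75th percentile 5, 4, 0.155 and 100% (2 of 2 genes). A threshold of 1.5-fold gave 648 higher and 487 lower genes, and one of 3-fold 8 and 9. The 3 other scalings kept both counts within 1.5 times (100 to 112 higher, 80 to 96 lower), and all 73 lower genes remained under each. The SHISA2 log2 ratio ranged from -1.26 to -1.22. The numbers of lists above and below the random range were 4 to 8 and 5 to 8 over 9 alternatives. The G2/M, G1/S, cholesterol and interferon lists stayed outside in all 9, with G2/M medians of -0.49 to -0.42 and interferon medians of 0.13 to 0.18. Every other list outside in the main setting came within its range, or had too few measured genes, in at least 1 alternative. When probe sets were averaged, the Wnt ligand, basal prostate and ribosomal protein lists (medians 0.53, 0.33 and 0.10) also lay above their ranges and the integrin list (-0.15) below, and with the 25th percentile floor the cancer-testis list (0.37) lay above. Of the other list medians and named genes under each alternative, 199 of the list values moved by less than the SD of random lists and 37 by more, and 995 gene values by less than the technical SD and 56 by more. No list outside its range and no 2-fold named gene changed sign. Signal over background limits the counts, since the technical SD was larger at each lower floor. No paired analysis was possible because each group holds 1 array.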

Other observations

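The 5 lists in this part were written after the 25 highest and 25 lowest genes with a mean signal above 800 had been seen, along with the genes of largest ratio under the naming rule, of which SPARC and DHX58 are in these lists, so each is also given without those genes. Genes named in this part were chosen after their values were seen. The tests of a slower culture, of a vector response and of independent noise were also chosen only after the results were seen.

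Basement membrane genes were lower in the knockdown array, with 16 of 20 below 0 and a median log2 ratio of -0.54. The network collagens COL4A1 (-0.79, and -0.04 on its other probe set) and COL4A2 (-0.94), the laminin chains LAMB1 (-0.78) and LAMC1 (-0.73, and -0.19 on the other), nidogen, NID1 (-0.75, and -0.40 on the other), and nephronectin, NPNT (-1.03), were all bright, and FBLN1 read -1.09 with probe sets from -1.26 to 0.29. LAMB3, a chain of the epithelial laminin that anchors hemidesmosomes, was higher at 0.80 and the perlecan gene HSPG2 at 0.37. A hypothesis is that the list merely gathers the extreme genes that prompted it. The 12 genes not seen beforehand had a median of -0.4059, at the 0.01th percentile of random lists, so that choice alone does not account for the shift, and why these genes were lower was not tested.

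Histone genes, mostly of the clustered families whose messages are normally made in S phase and lack a poly(A) tail, were higher, with 14 of 16 above 0 and a median of 0.52 (0.48 without the genes already seen), each above all 10000 random lists. H2AC6 read 0.82, H2BC5 0.66, H2BC6 0.57 and H2BC21 0.57, the dimmest of them at 585.1 in the control array, whereas the linker histone H1-10 read -0.27. How well the 3' labelling kit reads messages without a poly(A) tail was not tested, which limits what these signals mean. The histone list was not rerun without probe sets that can share probes, nor under the other scalings. Genes of type III interferons, chemokines and nucleic acid sensing had a median of 0.38 with 18 of 21 above 0, above all 10000 random lists, and 0.19 without the genes already seen, at the 99.7th percentile. Both versions hold CXCL10 of the interferon-stimulated list and CCL20, CXCL1, CXCL2, CXCL3 and CXCL8 of the NF-kB list. Neither is therefore independent of those earlier results. CCL5 (10724 against 6291, 0.77), RSAD2 (16193 against 10264, 0.66), IFNL1 (0.90), IFNL2 (0.74) and CXCL10 (0.40) were higher, CXCL8 (0.06) and CXCL1 (-0.06) near 0. Inhibitors of cyclin-dependent kinases and pocket proteins had a median of -0.08, at the 14.6th percentile, and of -0.10 without CDKN2B, the member already seen, at the 11.7th. Within that list CDKN2B read 1.01, CDKN2A 0.59 and CDKN1A 0.33, and RBL1 -0.61.

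Genes of the Fanconi anemia pathway and of homologous recombination were lower with the cell cycle lists, at a median of -0.38 with 17 of 19 below 0. XRCC2 (-0.94), RAD51AP1 (-0.77), FANCI (-0.67, with probe sets up to -0.10), BLM (-0.64) and FANCG (-0.64) led the list. The hypothesis that they share the shift of S-phase genes predicted a median below the random range without RAD51AP1, the member seen beforehand. It was -0.3746, below all 10000 random lists. Leaving out 1 of 19 genes could hardly move the median into the range, so this does not test the hypothesis. A shared shift was not separated from a cause specific to repair genes.

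The lower signals of cell cycle genes were set against 3 technical explanations. Under the 3 other scalings the G2/M median was at most -0.4231, below the random range in each. This cannot decide on scaling as a cause, because median centring moves a list and its random lists alike. Quantile normalization and loess change ratios by signal, on which the random lists were matched. The values show that G2/M genes were lower than other genes of like signal. Dim probe sets are argued against, since 29 of the 30 G2/M genes were still measured with the floor at the 75th percentile (387.3). Their median was -0.4361, which with so few genes lost had little room to move. A slower or denser culture unrelated to SHISA2 cannot be told apart from an effect of the knockdown, because there was 1 array per group.

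The median of the interferon-stimulated list was at least 0.129 under the 3 other scalings and above its random range in each. As for the cell cycle genes, this cannot decide on scaling and shows only that the list was higher than genes of like signal. A response to the transfected vectors, which may differ in strength between the groups, cannot be told apart from an effect of SHISA2. No untransfected cells were among the arrays, and each group had 1 array. In the control array the median signal of interferon-stimulated genes stood at the 89.06th percentile of measured genes, but signals of different probe sets also depend on probe affinity, so this rank does not show such a response.

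Whether the 2-fold genes exceed independent noise in each probe set stays open. The share with all probe sets in 1 direction had a lower limit of 56.82%, above the 50% that noise gives for genes with 2 probe sets. Without _x_at and _s_at probe sets the interval was 40.8% to 73.6% and included that value, and this condition was added after the first result was seen. Both limits cover all 2-fold genes together, so they say nothing of a single gene.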
